A study of Mus musculus with 2 samples.

How the data were processed

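The data were 2 two-colour Agilent arrays of BV-2 cells, 1 for the control group and 1 for the OGD/R group. The deposited scanner files give fluorescence intensity per spot and channel, which Agilent Feature Extraction had background-subtracted, detrended and dye-normalized within each array with a linear and a lowess step, per the file headers. The median and local background intensities of each spot, before any correction, were also in the deposited files. Values were not scaled between arrays, per the file headers. Dye normalization removes a difference in the overall balance of the channels, so an array-wide change in IP/Sup cannot be read from these files. Before it, the median log2 IP/Sup was -0.77 in control and -0.69 in OGD/R. The authors also deposited a table of log2 values for 5702 small-RNA probes. Each of its columns equals the log2 processed signal minus a constant, which is 11.9 for Sup and 14.2 for IP in control, and 11.5 and 13.8 in OGD/R. The column medians are -2.48 and -4.74 in control and -2.18 and -4.39 in OGD/R, in the same order. The origin of the constants and the filter behind the table are not given in the sources used here, and 4893 of its probes were well above background in both channels on both arrays, 18 of them with a spot marked as an outlier. The median over probes of the difference between arrays in that table is 0.26 in Sup and 0.34 in IP before any scaling.

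The 15742 spots of each array included 57 spots marked as outliers in control and 83 in OGD/R, which were left out, as were control spots. There were 0 saturated spots. The 102 spike-in probes, taken as such from their identifiers, were kept apart from the RNAs. Both arrays were read in 1 scan of 1 slide, so slide and scan do not part the groups. Signals of repeat spots were averaged on the log2 scale. A probe counted as well above background in a channel when at least 50% of its retained spots did. The log2 ratio of Cy5 (IP) to Cy3 (Sup) processed signal was centred on the array median over RNAs well above background in at least 1 channel on both arrays, without loess. Single-channel signals were scaled by the 75th percentile, taken for IP over probes detected in that channel on both arrays, for Sup over all non-control probes and for the sum of the channels over the RNAs that passed the filter. The spike-in probes differed by a median of -0.40 in Sup and -0.19 in IP before scaling.

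Differences are OGD/R minus control. With 1 array per group they are described by size, with a threshold of 2-fold, and no p-value was computed. The SD over repeat spots and the scanner's own error measure technical error only. The number of arrays limits the precision. A median over probes has a 95% binomial order-statistic interval, which describes the spread over probes. A group of gene probes was placed among 10000 random lists of small-RNA probes of the same size, matched on signal in 10 bins. The bins are broad at the top, where 18 of the 41 gene probes fell in the brightest bin. Lists with fewer than 5 members have values only.

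The rule for named RNAs, set before the data were examined, took the 10 largest differences of the ratio in each direction and the 5 largest of the total signal, all at least 2-fold, and members of fixed lists. After the files were seen it was narrowed to RNAs measured in both channels on both arrays, since signals near background have no order. Other small RNAs it took are not printed, because their identifiers have no names here. Gene symbols came from a RefSeq table of the mouse assembly GRCm38.p6 by accession, which named 46 of 50 gene probes, and no coordinates were used.

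The computation was tested on simulated data. Spot noise was drawn from repeat-spot probes, and 200 small-RNA probes per draw received a known change. Among the 4875 probes measured in both channels, 51.6% of 2-fold, 96.7% of 3-fold and 99.6% of 4-fold changes of the ratio passed the threshold. The noise simulation was run in a first version that drew normal values with the spot SD of all repeat-spot probes, dim ones included. It was replaced, after its counts had been seen, by residuals resampled from repeat-spot probes that pass the same filter. For probes measured in both channels, the dimmest signal bin held only 16 such residuals and the next 81. The shares of recovered changes above rest on the same residuals. The counts of both versions are reported because they lead to different readings. Alternatives set before the data were examined covered the background correction, loess, the centring, the scaling, the filter, the authors' table, repeat spots, thresholds and random lists. The planned normexp correction on mean signals used the median signals, as the scanner files used here hold no mean spot signal. These signals precede the scanner's detrending and dye normalization, so the settings with normexp also leave out those steps of the scanner. Loess on the processed signals without normexp, and random lists drawn from the setting they are compared with, were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and R 4.3.3 with limma 3.58.1 for normexp (offset 50) and loess (span 0.3).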

Results

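The series holds 2 two-colour microarrays of BV-2 cells, a mouse microglial cell line. One array came from cells kept under normal culture conditions (control). The other came from cells taken through oxygen and glucose deprivation followed by a return to normal oxygen and medium (OGD/R), a culture model of ischemia and reperfusion. The deprivation lasted 2 h in 5% CO2 and 95% N2 at 37 °C, and the length of the reoxygenation is not given in the sources used here. On each array the immunoprecipitated, modified RNA (IP) was read in Cy5 and the unmodified RNA left in the supernatant (Sup) in Cy3. Which modification the antibody recognised is not given in the sources used here. There was 1 array per group, so no difference between the conditions has a replicate check, and no test between them was made.

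Each array carried 14400 small-RNA probes of 1 spot each and 50 gene probes of 10 spots each. The identifiers of the small-RNA probes carry 5 tokens, namely MIRNA (3487 probes), MIRNASS (2945), TRF (3633), TRFSS (3213) and PST (1122). The files used here do not pair these identifiers with RNA names or explain the tokens, so single small RNAs are given by identifier. Accessions gave symbols to 46 of the gene probes. Whether each of these probes reports only the transcript it is named for was not tested. In the control array 51.7% of the small-RNA probes were well above background in Sup and 40.2% in IP, and in the OGD/R array the shares were 51.9% and 40.0%. The negative control spots had a median processed signal of 28.8 in Sup and 31.7 in IP on the control array, against 27.5 and 31.0 on the OGD/R array.

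The first comparison asked which RNAs had a different balance of modified to unmodified RNA after OGD/R, read as the median-centred log2 IP/Sup. Among the gene probes with symbols, that of Apoe, the apolipoprotein E gene that microglia express, had a ratio 3.37-fold higher in OGD/R. Its log2 difference was 1.75, with an SD of 0.06 over repeat spots. Such spot SDs hold only the scatter within each array and not error between arrays. Gsdmd, which encodes the pore-forming protein of pyroptosis, was 2.63-fold higher, with a log2 difference of 1.40 and a spot SD of 0.06. E2f1, a transcription factor of the cell cycle, was 2.68-fold higher, with a log2 difference of 1.42 and a spot SD of 0.21. The predicted gene Gm9789 differed by 1.36, with a spot SD of 0.18. The ratio was lower in OGD/R for Cep41, which encodes a centrosomal protein, at -1.10 with a spot SD of 0.36. It was also lower for Rab5a, an early endosome GTPase, at -0.92 with a spot SD of 0.17. The largest fall among the gene probes was that of a probe without a symbol here, at -1.58 with a spot SD of 0.57. On the OGD/R array 5 of its 10 spots were well above background in each channel. With normexp background correction, a setting that also leaves out the scanner's dye normalization, Apoe differed by 1.12 and Gsdmd by 1.08. In that setting E2f1 at 0.88, Gm9789 at 0.46 and Cep41 at -0.15 fell short of 2-fold and Rab5a differed by -0.59. With normexp and loess none of the 6 named genes reached 2-fold. They differed by 0.78 for Apoe, 0.89 for Gsdmd, 0.86 for E2f1, 0.43 for Gm9789, -0.16 for Cep41 and -0.70 for Rab5a.

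The channels behind these ratios differed from gene to gene. The Apoe ratio followed its supernatant, where scaled Sup signal differed by -1.82 and IP signal by -0.01. The IP share of the Apoe signal was 57.4% in control and 81.7% in OGD/R, from the dye-normalized processed signals before median-centring. Gsdmd likewise had a Sup difference of -1.29 and an IP difference of 0.16. E2f1 showed the opposite arrangement, with an IP difference of 1.34 and a Sup difference of -0.14. Cep41 had a higher Sup signal in OGD/R, by 1.13, and an IP difference of 0.09. Its control Sup signal was 7.14 on the log2 scale, with 8 of 10 spots well above background. The lowest Sup signal well above background on that array was 6.82. Gpi1, which encodes a glycolytic enzyme, had a ratio difference of 1.32 with a Sup difference of -1.12. The class I histocompatibility genes H2-M2 and H2-Q7 had ratio differences of 1.31 and 1.20, but probes of this family can bind related transcripts. The ratio differences of Gpi1, H2-M2 and H2-Q7 fell short of 2-fold with normexp (0.93, 0.58 and 0.46) and with normexp and loess (0.63, 0.33 and 0.19), and that of H2-Q7 also centred on the spike-in probes (0.97). Gpi1, H2-M2, H2-Q7, Cep41 and Rab5a were chosen for mention after their values were seen.

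As a group, the gene probes had a higher IP/Sup ratio in OGD/R. Of the 34 gene probes measured in both channels on both arrays, 29 had a higher ratio and 5 a lower one. In 28 of the 34, counting either direction, the repeat spots of the arrays did not overlap. At least 2-fold higher ratios were found in 9 of them and 2-fold lower ratios in 2. Of the 36 spike-in probes measured in both channels on both arrays, 25 also had a higher ratio. Differences of the spike-in probes ran from -0.59 to 2.10, which is above the 1.75 of Apoe. Over the 41 gene probes with at least 1 channel well above background, the median difference was 0.59 (95% interval over probes 0.21 to 0.86). That median lay at percentile 100 of 10000 random lists of small-RNA probes matched on signal, whose medians ran up to 0.35. Their median Sup difference was -0.61 (interval -1.09 to -0.29) and their median IP difference -0.07 (-0.29 to 0.24). The Sup median was -0.11 with normexp, -0.10 with normexp and loess, -0.39 with no filter and -0.20 with the spike-in probes as the scale, where its interval reached 0.13. The median ratio difference was 0.16 with normexp, 0.37 with no filter, 0.10 with normexp and loess, and 0.36 centred on the spike-in probes. The intervals of the last 2, -0.02 to 0.33 and -0.03 to 0.62, reach below 0.

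**Figure D1:**
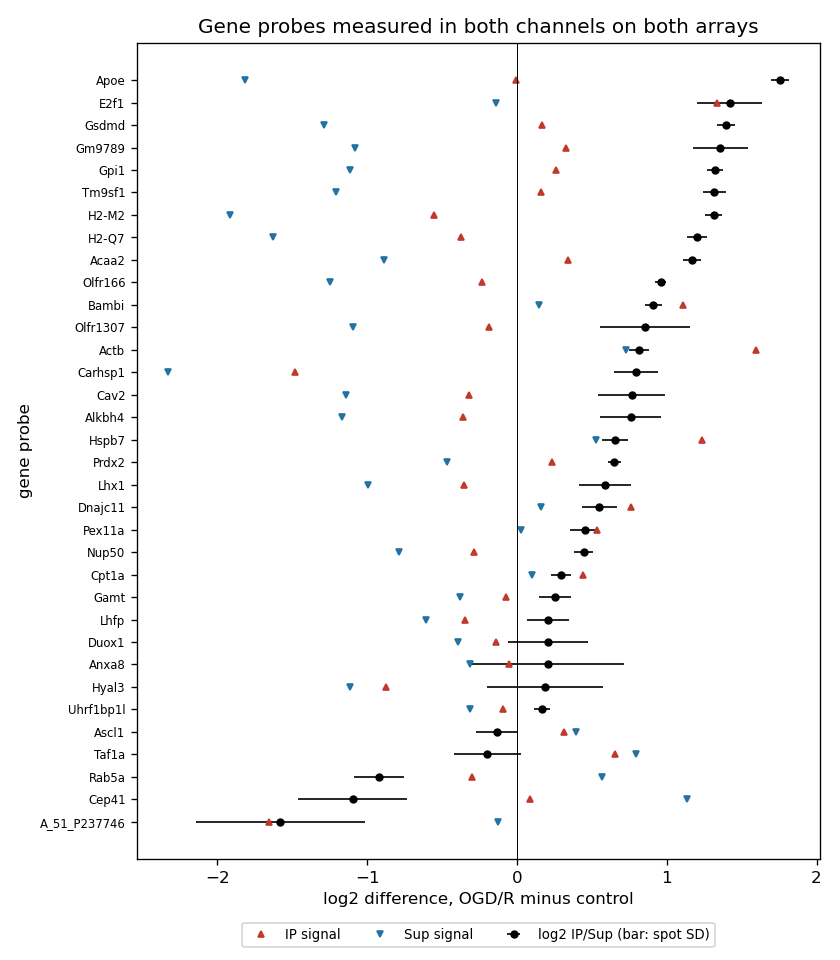
Each row is a gene probe measured in both channels on both arrays, and the horizontal axis gives the log2 difference, OGD/R minus control. Black points are the log2 IP/Sup ratio with the SD over repeat spots, red triangles the IP signal and blue triangles the Sup signal, from Apoe at 1.75 down to an unnamed probe at -1.58.

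The fixed lists held few of these genes. Of 27 lists, 4 had a match, with 1 gene each, so values are given without a percentile. Apoe stood for the microglia genes and Gsdmd for the cell death genes, with the values above. Atg3 of the autophagy genes and Mbp of the astrocyte and oligodendrocyte genes had Sup signals not well above background on both arrays, so no ratio difference is given for them. The 16 lists of small RNAs had no match, because the files used here hold no small-RNA names.

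Among the small-RNA probes the ratio profiles of the arrays were alike. Over the 4875 probes measured in both channels the centred ratios correlated at Pearson r = 0.95 (Spearman rho = 0.94) across probes, which are not independent replicates. Over these probes the class medians of the ratio difference lay between 0.03 and 0.08. Among these probes the largest difference upward belonged to the probe ASMM10SM20TRFSS100009099TV2, 3.60-fold higher in OGD/R, with a log2 difference of 1.85 and a scanner error of 0.32. The largest downward belonged to ASMM10SM20MIRNA100000388TV2, 3.76-fold lower, with a log2 difference of -1.91 and a scanner error of 0.49. Its control Sup signal, from 1 spot, was 6.96 on the log2 scale. That is close to 6.82, the lowest Sup signal well above background on the control array. With normexp and loess the upward and downward probes differed by 0.84 and -0.41, and with normexp by 0.90 and -0.36, which is less than 2-fold.

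Counting all 7470 RNAs well above background in at least 1 channel, 319 had a ratio at least 2-fold higher in OGD/R and 446 at least 2-fold lower. Without the gene probes the counts were 309 and 444, and spot noise alone gave 269 and 266 in simulations. Most of these RNAs had a channel near background. Among the 4875 small-RNA probes measured in both channels, 57 were higher and 43 lower. For this set, spot noise gave 28 in each direction when it was taken from repeat-spot probes measured in both channels, but 97.9 higher and 100.4 lower when it was taken from all repeat-spot probes. The second of these models gave more calls from noise alone than were observed, so it overstates spot noise for this set. The first rests on few residuals at low signal. Whether these 57 and 43 exceed spot noise is thus not settled. Over all RNAs the counts were 10 and 5 with normexp, 7 and 11 with normexp and loess, and 182 and 698 centred on the spike-in probes. The authors' table, which holds small-RNA probes only, gave 127 and 127.

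**Figure D2:**
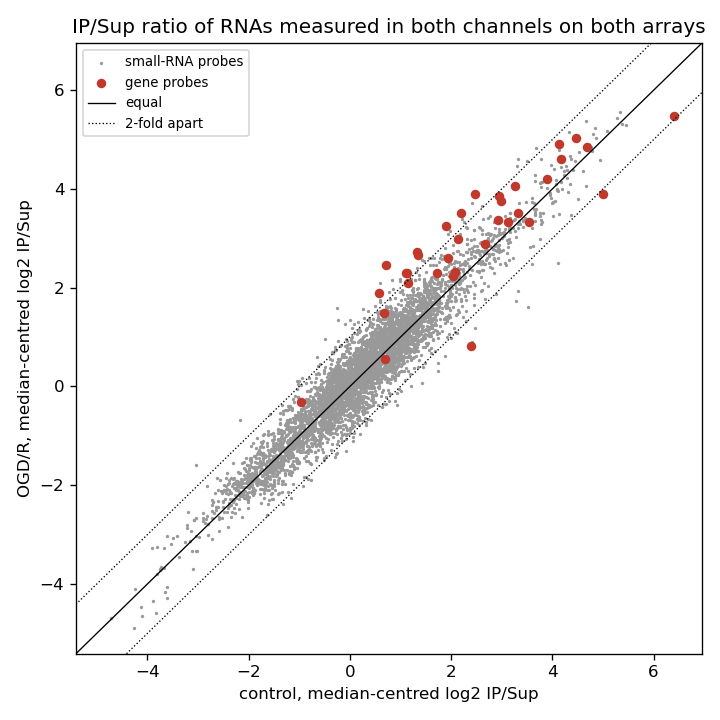
Median-centred log2 IP/Sup of each RNA measured in both channels, with the control array on the horizontal axis and the OGD/R array on the vertical axis. Grey points are 4875 small-RNA probes, red points 34 gene probes, the solid line marks equal ratios and the dotted lines a 2-fold difference, and 29 of the red points lie above the solid line.

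The second comparison asked which RNAs differed in total signal, the sum of both channels scaled between arrays, as a stand-in for abundance. The sum depends on the labelling and dye normalization of each channel, so a change in 1 channel alone can move it. Actb, the cytoplasmic beta-actin gene, had a higher total signal in OGD/R, with a log2 difference of 1.25, though its probe can bind other actin transcripts. E2f1 differed by 1.11 and Hspb7, a small heat shock protein gene, by 1.05. Both fell short of 2-fold with normexp, at 0.59 and 0.87, and with normexp and loess, at 0.62 and 0.86. The E2f1 total followed its IP signal, which differed by 1.34, while its Sup signal differed by -0.14. Carhsp1, which encodes a cold shock domain protein, had a lower total signal, with a log2 difference of -1.60, and both its channels were lower. Apoe differed by -0.57, or by -0.32 with the spike-in probes as the scale, and Gsdmd by -0.22, or by 0.04 on that scale and -0.37 with normexp. Actb and Hspb7 were chosen for mention after their values were seen.

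TRF probes made up 49 of the 93 RNAs with at least 2-fold higher total signal and 4 of the 63 with at least 2-fold lower. MIRNA probes made up 16 of the higher and 20 of the lower, MIRNASS probes 16 and 12, TRFSS probes 8 and 20, and PST probes 1 and 5. The median total difference of the 2234 TRF probes was 0.08 (95% interval 0.06 to 0.09), against -0.04 for the MIRNA, -0.01 for the MIRNASS, -0.03 for the TRFSS and -0.03 for the PST probes. The TRF median was 0.039 with normexp, 0.036 with normexp and loess, 0.050 with median scaling, 0.043 with the percentile over the other probes, 0.019 in the authors' table and 0.34 with the spike-in probes as the scale. A change of scale moves all probes alike. The median over all small-RNA probes was 0.004 in the main setting, -0.026 with median scaling and 0.26 with the spike-in probes as the scale. It was 0.025 with normexp and 0.020 with normexp and loess. Among the RNAs measured in both channels, the probe ASMM10SM20TRFSS100000164TV2 had the highest total difference, 1.52. The lowest was that of ASMM10SM20MIRNA100005291TV2 at -4.36, a 20.5-fold lower signal in OGD/R seen in both channels and on 1 spot per array. With normexp these differed by 0.48 and -2.64, and with normexp and loess by 0.50 and -2.53. In simulations with the replacement noise model, spot noise alone gave 9 small-RNA probes in each direction, against 90 higher and 61 lower observed. The first version was not run for the total signal. Spot noise also leaves out technical differences between the arrays, so these counts cannot be set apart from such differences. The higher and lower counts over all RNAs were 8 and 14 with normexp and also with normexp and loess, and 308 and 22 with the spike-in probes as the scale. They were 36 and 38 over the RNAs with both channels well above background, and 44 and 71 over the small-RNA probes of the authors' table.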

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

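Of the tests given here, those on spike-in probes, on spot overlap and on probes near background were chosen after their results had been seen, as were loess without normexp, the random lists of the corrected values and the intervals of the ratios of calls. Signals outside the main measurement were read from the control and spike-in probes, of which 66 were measured in IP and 55 in Sup. The Agilent positive control (+)E1A_r60_a107 had an IP signal higher on the OGD/R array than on the control array by 1.77 on the log2 scale (20 spots). The control (+)eQC-41 had a higher Sup signal by 1.46 (6 spots), and the spike-in probe ASSPINKEIN100002554 had a higher Sup signal by 1.34 (3 spots). Others were at least 2-fold lower on the OGD/R array, 1 in IP and 4 in Sup: the spike-in probes ASSPINKEIN100004873 by -3.01 in Sup, ASSPINKEIN100003937 by -1.85 in IP and -1.80 in Sup and ASSPINKEIN100008369 by -1.05 in Sup, and the control (+)eQC-40 by -1.27 in Sup.

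The higher IP/Sup ratio of the gene probes in OGD/R may be technical in part, though spot noise is argued against. The repeat spots of the arrays did not overlap for 28 of 34 gene probes, counting either direction. These 28 include Rab5a, Cep41 and a probe without a symbol, whose ratios were lower in OGD/R. Signal-dependent dye normalization cannot be told apart: after normexp and loess the median was 0.10, which met the criterion set beforehand, but the random lists of that criterion came from the main setting, and that correction shrank the spread of all ratio differences to 28.8%. Among lists of the corrected values the median lay at percentile 99.99, yet its interval of -0.02 to 0.33 reached below their upper bound of 0.03. Loess without normexp left 0.59 (0.29 to 0.81), at percentile 100 of lists of that setting, whose medians ran up to 0.29. With normexp alone the median of 0.16 also lay at percentile 100 of such lists, which ran up to 0.15. A shift shared by all probes with repeat spots cannot be told apart either, because the spike-in median was 0.20 with an interval of 0.01 to 0.47, which overlaps that of the gene probes. A difference between the cells stays open and untested with 1 array per group.

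The higher total signal of TRF probes in OGD/R was small but set them apart from other small-RNA probes. In the authors' table the TRF median was only 0.019, but the median of the other probes there is not given here. A signal-dependent difference between the arrays is argued against, as the TRF median of 0.08 lay at percentile 100 of matched random lists of other small-RNA probes. These lists treat probes as independent, and whether related TRF probes share signal was not tested. Uneven signal over the array surface is argued against as well, since TRF probes exceeded the others in all 4 regions of equal size into which the array was divided, by at least 0.098. Differences in RNA preparation, labelling or the cells could each remain, and none was tested.

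The excess of small-RNA probes with a 2-fold lower ratio over those with a higher one was not explained by the tests made. Among probes measured in both channels, lower calls were 0.75 times the higher ones (95% binomial interval 0.50 to 1.14). That set, however, leaves out probes whose signal was not well above background in a channel of either array. Simulated spot noise over the wider set, dim channels included, gave 269 higher and 266 lower. Small-RNA probes were also split by signal into 4 groups of 1857 or 1858. Lower and higher calls were 275 and 196 in the dimmest group and 124 and 68 in the next. They were 39 and 32, then 6 and 13, in the brighter groups, so the excess lay mainly at low signal. The median ratio difference rose from -0.06 in the dimmest group to 0.07 in the brightest. Low signal goes with both a channel near background and dye normalization at low signal. A channel near background thus cannot be told apart. For dye normalization at low signal, normexp and loess left 11 lower and 7 higher calls, a ratio of 1.57. The criterion set beforehand counts a ratio of at least 1.3 against it. With so few calls, however, the 95% binomial interval runs from 0.56 to 4.78. Loess without normexp left 381 lower and 262 higher calls among the small-RNA probes, so the excess remained under that correction. That setting was not part of the criterion, and dye normalization at low signal cannot be told apart.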

How the results depend on the processing

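Loess on the processed signals and random lists drawn from the setting they are compared with were chosen after the data were seen. The noise model of the main results replaced a first version after the counts of that version had been seen. Apart from the noise models, the other alternatives were set before the data were examined. The counts depended strongly on the processing. RNAs with a 2-fold higher and lower ratio, 319 and 446, came to 10 and 5 with normexp, 7 and 11 with normexp and loess, 182 and 698 centred on spike-ins, 66 and 45 when both channels had to be well above background, 1116 and 1252 with no filter, 127 and 127 in the authors' table (small-RNA probes only), 901 and 1032 at 1.5-fold, and 79 and 133 at 3-fold. RNAs with a 2-fold higher and lower total, 93 and 63, came to 8 and 14 with normexp and also with normexp and loess, 308 and 22 with spike-in scaling, 36 and 38 with both channels well above background, 388 and 278 with no filter, 582 and 360 at 1.5-fold, and 6 and 11 at 3-fold, and 44 and 71 in the authors' table.

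The gene probes' median ratio difference of 0.59 stayed above 0 in the 10 alternatives run, from 0.10 to 0.65, and was 0.16 with normexp, 0.10 with normexp and loess (interval -0.02 to 0.33) and 0.36 centred on spike-ins (-0.03 to 0.62). Their Sup difference of -0.61 was -0.11 with normexp, -0.10 with normexp and loess and -0.20 with spike-in scaling. Their total difference of -0.23 turned to 0.029 with spike-in scaling, so its direction rests on the scale. The TRF median total difference of 0.080 was 0.039 with normexp, 0.036 with normexp and loess, 0.043 with the percentile over the other probes, 0.063 with quantile normalization, 0.060 with both channels well above background, 0.050 with median scaling, 0.34 with spike-in scaling and 0.019 in the authors' table. The MIRNA median ratio difference of 0.029 turned to -0.012 with normexp and loess and to -0.20 centred on spike-ins. The median total difference of all small-RNA probes was 0.004 in the main setting, -0.026 with median scaling and 0.26 with spike-in scaling. The TRF median moved along with it under these changes of scale. The median ratio difference of all small-RNA probes was -0.21 centred on spike-ins. Spot noise gave 97.9 higher and 100.4 lower in the first version of the noise model, against 27.8 and 27.9.

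With normexp the SD of the ratio difference among the 1858 dimmest probes was 0.10 in place of 0.88. That setting used the median signals before the scanner's detrending and dye normalization, changed the background correction and added an offset. The bright Apoe probe, with log2 signals from 17.2 to 19.6, also moved, from 1.75 to 1.12. The part due to each of these steps was not tested. The cause of the other changes was not tested either. Leaving out saturated RNAs removed nothing, as there were 0 saturated spots, and each RNA identifier had 1 probe, so these alternatives were not run. No paired analysis was possible because each group has 1 array.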

Other observations

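Bambi, a decoy receptor of the TGF-beta family, had a ratio difference of 0.91 with an IP difference of 1.11 and a Sup difference of 0.15. Prdx2, which encodes a peroxidase, had a ratio difference of 0.65 and the IP share of its signal was 29.8% in control and 39.6% in OGD/R. Trp53rka had a Sup signal well above background in control and not in OGD/R, so its ratio has only a bound. Probes for genes known mainly from other cell types also gave signal in both channels. Among them were Olfr166, an olfactory receptor gene, with a ratio difference of 0.96, and Lhx1, a developmental transcription factor gene, with 0.59. The Olfr166 probe had an IP signal of 13.7 on the log2 scale in control, against 14.5 for Actb. With normexp and loess the ratio differences were 0.63 for Bambi, 0.23 for Prdx2, 0.60 for Olfr166 and 0.11 for Lhx1. No test of cross-hybridisation was made. These genes were chosen after their values were seen.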
